A study of Mus musculus with 2 samples.

How the data were processed

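Total RNA from cochleae of 7-week-old female C57BL/6 mice, an inbred laboratory strain, was measured on 1-colour Agilent mouse expression arrays, 1 array per sample. The noise sample came from mice exposed to intense noise for 2 hours and dissected 3 hours after the exposure, and the baseline sample came from mice without noise exposure. Per the labels' protocols, Cy3-labelled cRNA was made from 0.1 micrograms of RNA with a low-input labelling kit. The labels used here give neither the number of mice behind each sample nor the clock hour of dissection. Per the file headers, both arrays lay on the same slide and were read in the same scan, so no slide or scan separated the groups.

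The authors' deposited scanner files hold spot intensity values. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, which subtracted a background, detrended each array and gave spots near background a small positive surrogate value. The processed signal was the unit used here, on a linear scale and not scaled between arrays. The authors' deposited value table holds log2 values of the same arrays, and its scale, centring and direction were worked out from the values. Each column equalled log2 of that array's own processed signal, set to at least 1, minus a constant of 8.30 (noise) or 8.12 (baseline) that placed the column's 75th percentile at 0. Its column medians were -2.81 (noise) and -2.79 (baseline), and there was no centring per gene, so its scale was the same as the main one used here.

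Of the 62976 spots on each array, 59305 were not controls and carried 56605 probes of 60 bases, of which 300 were printed 10 times each. Outlier flags removed 77 non-control spots of the noise array and 58 of the baseline array, which left 56590 probes on both arrays. No spot was saturated. Spots of a probe were averaged on the log2 scale, and each array's 75th percentile over non-control probes was subtracted. A probe counted as measured where the scanner software called it well above background on both arrays, which held for 41647 probes. A gene took the median log2 ratio (noise minus baseline) of its measured probes. Gene names were those of the array design and can be old. The RefSeq table of assembly GRCm38.p6 held the accessions of 32994 probes, and for 1535 of these its current symbol differed from the array's name. Probe coordinates are on the mm9 assembly, per the file headers. The annotation of that assembly was not used here, so exon or untranslated-region positions are not given.

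Each group had 1 array, so there was no replicate error, no p-value was computed, and a size rule of 2-fold was used in its place. The number of arrays limits the precision. The technical spread within and between probes could be measured. The median SD of log2 signal between repeat spots was 0.046 on the noise array and 0.051 on the baseline array. A log2 ratio had an SD of 0.071 from repeat spots alone. Different probes of a gene differed in their log2 ratio with an SD of 0.27, over 9348 genes with at least 2 measured probes. For a gene well above background on only 1 array, the bright level was set against the higher of the dim probe's own level and the lowest level among probes well above background on the dim array, and the result is given as an at-least fold.

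The samples' groups, the 2-fold rule, 29 gene lists, the rule for named genes and the processing alternatives were fixed before the data were examined. Among genes measured on both arrays with a standard symbol, a mean level at or above the 25th percentile of measured genes and all measured probes in the same direction, the 12 with the highest and the 8 with the lowest log2 ratio were named. Without these level and probe criteria, the rule also took the 4 largest at-least folds in each direction among genes well above background on 1 array only and up to 3 members of each list by absolute log2 ratio. Predicted genes, clone and accession names, locus names, microRNA hosts, long intergenic RNAs and pseudogenes did not count as standard symbols. Other list members past 2-fold that are named were chosen after their values were seen, and a few genes that the rule takes are not reported here. Of the 593 list entries, 591 were matched to a name on the array, 9 of them from entries that gave alternative symbols, and 10 genes stood in more than 1 list.

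Each list's median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean level so that levels matched. A list stood apart where its median lay outside the central 95% of the random medians, and 1.45 of 29 lists would do so by chance. This describes the 2 arrays and is no test across animals. After the data had been seen, 6 further lists of tissue markers were written (adipocyte, pituitary, central neuron, choroid plexus, middle ear and airway epithelium, noradrenergic neuron), in part from genes already seen to differ. The gene and list steps were tested on simulated data made from these arrays. All of 50 genes set to a log2 ratio of 3 and all of 50 set to -3 passed 2-fold, as did 96% of 50 set to 1.5 and 98% of 50 set to -1.5. Of 26880 unchanged genes, 0.0074% passed. Every probe was given normal noise of the same SD, 0.26, and the baseline array's background calls were kept. Ratios of the measured genes had an SD of 0.35, so this share is no false-call rate for the real arrays. Of 100 unshifted lists of 20 genes, 5% lay outside the central range, and all of 100 lists shifted by 0.3 were found above it. The unshifted lists came from the same genes as the random lists, so a share near 5% was fixed in advance.

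The alternatives were median scaling, quantile normalization, loess on level, a normexp background correction with an offset of 50 on the mean and local background signals, the authors' table, no filter on dim probes, a stricter filter at 4 times the lowest signal well above background, the brightest probe of each gene, 1.5-fold and 3-fold rules and random lists not matched on level. Scaling to the 8 spike-in probes well above background on both arrays, and counts without the tissue marker lists or the clock genes, were added after the data had been seen. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.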

Results

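The cochlear transcriptome of mice 3 hours after 2 hours of intense noise was compared with that of mice without noise exposure, to find which transcripts differ early after acoustic trauma. There was 1 array per group and therefore no replicate, so every difference below is between 2 samples and none was tested across animals. The arrays were of similar brightness. On the noise array 75.3% of probes were well above background, with a 75th percentile of the processed signal of 316, and on the baseline array 75.2% were, with a 75th percentile of 278. Both samples are labelled female: Xist, the transcript that silences an X chromosome, had signals of 271 (noise) and 268 (baseline), and no probe of the Y-linked genes Ddx3y, Uty and Eif2s3y was well above background. Of 6 probes for Y-linked Kdm5d, 1 was well above background, with similar signals on both arrays (114 and 122).

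Among genes measured on both arrays that met the symbol, level and probe criteria for naming, Hmox1, the inducible heme oxygenase, was highest at 3 hours after noise, 17.7-fold (processed signal 1915 against 95.1). In this ranking it was followed by Gdf15, a stress-induced cytokine, at 5.61-fold, by Tnfrsf12a, the receptor of the cytokine TWEAK, at 5.39-fold, and by the retinoid-binding protein gene Rbp7 at 4.93-fold. The monocyte chemokine genes Ccl7 and Ccl2 were 4.62-fold and 4.27-fold higher. In the opposite direction stood genes of other organs and of the central nervous system: Lipf, a lipase secreted by glands of the mouth and stomach, was 42.9-fold lower after noise, Bpifb1, a secreted protein of airway epithelium, 36.6-fold, the glycine receptor subunit gene Glra1 18.2-fold and the pituitary hormone gene Prl (prolactin) 11.4-fold.

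The remaining genes among the 12 highest of that ranking had log2 ratios between 1.95 and 2.19. They were Gem, a small GTPase, Helt and Sertad3, transcriptional regulators, Dbp, a clock output factor, Cyp39a1, an oxysterol hydroxylase, and Ier3, an immediate early gene. The 8 lowest were completed by Slc32a1, the vesicular transporter of GABA and glycine, at a log2 ratio of -3.25, Cga, the shared subunit of pituitary glycoprotein hormones, at 8.02-fold lower, growth hormone (Gh) at -2.89 and somatostatin (Sst) at -2.89. The probe for Hmox1 lies on chromosome 8 from 77624406 to 77624466, that for Gdf15 on chromosome 8 from 73153293 to 73153352, that for Lipf on chromosome 19 from 34051173 to 34051232 and that for Prl on chromosome 13 from 27156985 to 27157044 (mm9). A further Hmox1 probe was not well above background on either array, and with no filter on dim probes Hmox1 was 6.15-fold higher. With the normexp background Hmox1 was 11.8-fold, Sertad3 2.79-fold, Gem 2.76-fold, Ier3 2.55-fold, Helt 2.27-fold and Ccl7 2.17-fold higher. Bpifb1 was 11.2-fold, Glra1 9.64-fold, Slc32a1 6.11-fold, Lipf 5.10-fold, Sst 4.49-fold, Gh 4.33-fold and Cga 2.54-fold lower with it, and the 12 highest and 8 lowest genes all stayed past 2-fold. With the stricter filter on dim probes Lipf and Cga were no longer measured, and Bpifb1 was 20.5-fold lower, as with its brightest probe.

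**Figure D1:**
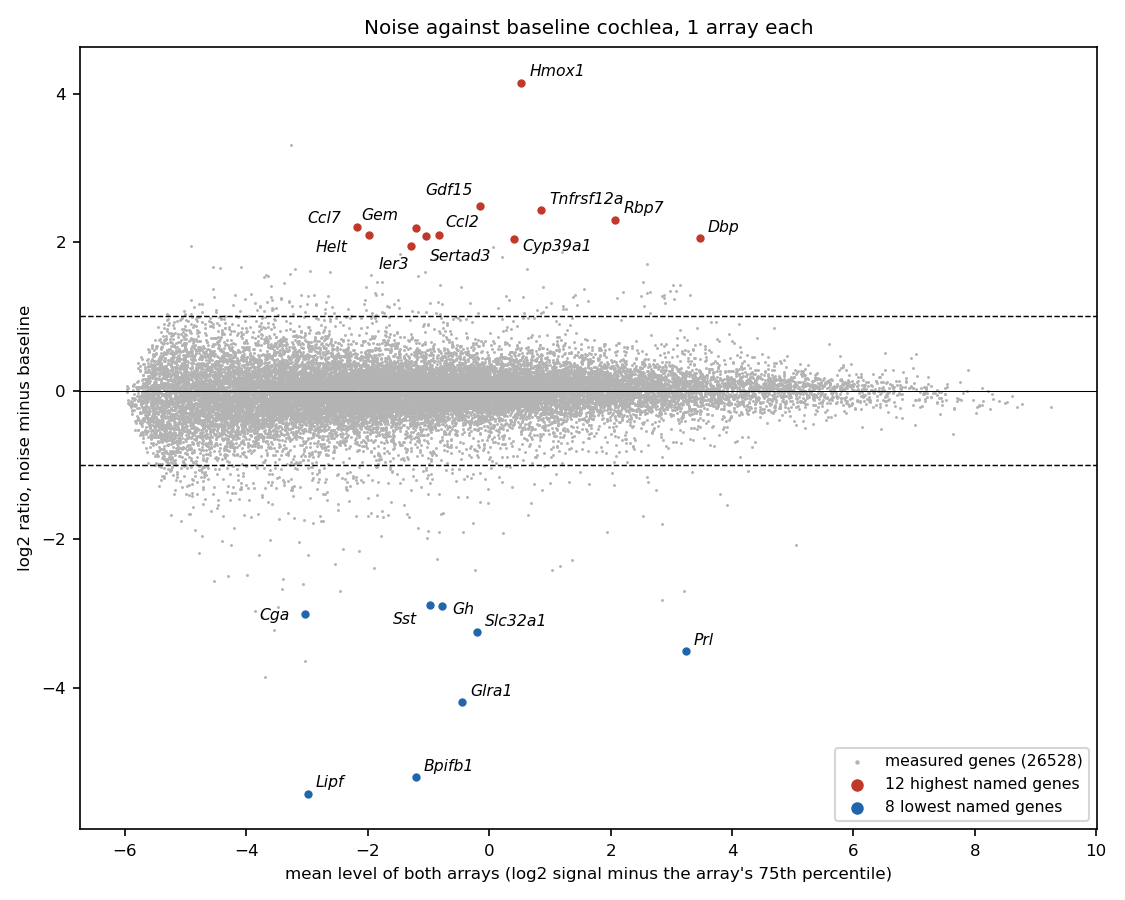
Log2 ratio (noise minus baseline) of each of the 26528 measured genes against its mean level over both arrays (log2 signal minus the array's 75th percentile), with the 12 highest named genes in red, the 8 lowest in blue and dashed lines at 2-fold. Hmox1 stands apart at 4.15, the other 11 red genes lie between 1.95 and 2.49, and the blue genes lie between -5.42 and -2.89.

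Over the 26528 genes measured on both arrays, 162 were at least 2-fold higher after noise and 332 at least 2-fold lower, so that 32.8% of the genes past 2-fold were higher. Log2 levels correlated across genes with r = 0.991 (genes are not independent replicates), and the central 95% of log2 ratios ran from -0.77 to 0.63. All 84 genes past 2-fold with several measured probes had every probe in the same direction. Selection by the gene's median ratio favours this, and probes could still differ in size, as for Pax5 (0.07 and 2.38). The split into higher and lower genes depended on the scaling. With spike-in scaling, added after the data were seen, 351 genes were higher and 186 lower (65.4% higher) and the median of all genes moved to 0.21, and with the normexp background 56 were higher and 74 lower (43.1% higher). Before scaling, the 8 spike-in probes differed between the arrays by -0.20 to 0.40 in log2, so they do not fix the offset closely.

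A further 619 genes were well above background on the noise array only and 547 on the baseline array only, and the at-least fold reached 2 for 33 and 94 of them. After noise, Slc6a2, the noradrenaline transporter, was at least 21.2-fold higher, Sdr16c5, a retinol dehydrogenase, at least 9.46-fold, Fosl1, an AP-1 subunit, at least 4.66-fold and the vomeronasal receptor gene Vmn1r212 at least 2.56-fold. At baseline, Dmbt1, a secreted mucosal glycoprotein, was at least 67.9-fold higher than after noise, the neuronal glycine transporter gene Slc6a5 at least 45.6-fold, the GABA transporter gene Slc6a11 at least 8.67-fold and the homeobox gene Evx1 at least 6.28-fold.

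Genes of the immediate early response were higher after noise as a group. Of 34 measured members, 27 had a log2 ratio above 0, 5 were at least 2-fold higher (Ier3 1.95, Maff 1.55, Fosb 1.20, Fos 1.07 and Atf3 1.06) and 2 at least 2-fold lower, Egr4 at -1.96 and Arc at -1.39, both neuronal activity genes. The list median was 0.45, against -0.08 to 0.09 in the central 95% of random lists. Fosl1 belongs to the same list and was measured on the noise array only. Egr4 (-0.47), Fosb (0.43), Atf3 (0.75) and Fos (0.99) were under 2-fold with the normexp background, as was Fosb with no filter on dim probes (0.80).

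Chemokine and cytokine transcripts were higher in part. Of 28 measured members, 5 were at least 2-fold higher, namely Ccl7 (2.21), Ccl2 (2.09), Cxcl10 (1.80), Il6 (1.65) and Cxcl1 (1.29), none was 2-fold lower, and 12 lay below 0, among them Il1b at -0.59. Tnf was at 0.06. The list median of 0.10 lay just above the random range (-0.13 to 0.09) and within it when each gene was represented by its brightest probe (0.062). With the normexp background it was 0.0074, still above its random lists, and Cxcl1 (0.46) and Il6 (0.25) were under 2-fold. With no filter on dim probes Cxcl10 was at 0.65.

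Target genes of inflammatory signalling also stood above the random range. The NF-kappaB feedback and adhesion list had a median of 0.24 (random range -0.13 to 0.11) with 16 of 20 members above 0 and none past 2-fold, Ptgs2, the inducible cyclooxygenase, being highest at 0.81. STAT3 and acute-phase genes had a median of 0.23 (-0.12 to 0.10), with 19 of 23 above 0 and 2 past 2-fold, Socs3, a feedback inhibitor of cytokine signalling, at 1.12 and Ch25h, an oxysterol-forming enzyme, at 1.05. Among interferon-stimulated genes 22 of 25 were above 0, with a median of 0.21 (-0.10 to 0.10), and 1, Bst2, was past 2-fold at 1.27, with Ifit3 at 0.98. With the normexp background Ch25h was under 2-fold (0.78), and the medians of the NF-kappaB list (0.11) and the STAT3 list (0.12) were smaller and still above their random lists.

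Stress pathways other than these were uneven. Unfolded protein response genes had a median of 0.24 (random range -0.09 to 0.11), with 20 of 23 above 0, none past 2-fold and Dnajc3 (0.59), Pdia3 (0.56) and Herpud1 (0.52) highest. In the antioxidant list Hmox1 alone of 21 genes was past 2-fold: Srxn1 followed at 0.49 and Gsr at 0.43, Nqo1 was at -0.02 and Gclm at -0.29, and the list median of 0.11 lay within the random range (-0.08 to 0.11). Heat shock genes had a median of 0.02 with none of 20 past 2-fold, hypoxia-induced genes 0.06 with none of 19, p53 and apoptosis genes 0.02 with 1 of 21, the apoptosis effector gene Bax (1.16), and cell cycle genes 0.08 with none of 25. All 4 medians lay within their random ranges. The matrix remodelling and wound response list (median 0.10, random range -0.11 to 0.11, 20 genes) held Adamts4, an aggrecan-cleaving protease, at -1.30. With the normexp background Bax (0.83) and Adamts4 (-0.68) were under 2-fold, as was Bax with its brightest probe (0.97).

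Circadian clock genes gave the highest median of the 29 lists, 0.73 against a random range of -0.14 to 0.13. Of 16 measured members, 5 were at least 2-fold higher after noise: Dbp (2.06), Nr1d1 (1.77), Per3 (1.42), Nr1d2 (1.27) and Tef (1.14), which encode clock repressors or output factors. Arntl, which encodes the clock activator BMAL1, was 3.26-fold lower (-1.70), with its 3 probes between -1.93 and -0.85, and was under 2-fold with the brightest probe (-0.85) and at -1.01 with the normexp background. Another activator gene, Clock, was at -0.01, and Npas2 was well above background on the baseline array only. Leaving the clock list out, as added after the data were seen, 157 genes were at least 2-fold higher.

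Glucocorticoid-induced genes, which respond to stress hormones, had a median of 0.53 (random range -0.10 to 0.11), with 15 of 19 above 0. Fkbp5, a co-chaperone of the glucocorticoid receptor, was past 2-fold at 1.19, with its 3 probes between 0.54 and 1.32, and was at 0.47 with the normexp background and 0.86 with the stricter filter. Map3k6 was at 0.86, Zbtb16 at 0.68 and Tsc22d3 at 0.60, while Angptl4, also a fat-cell and hypoxia-induced gene, was at -0.96.

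**Figure D2:**
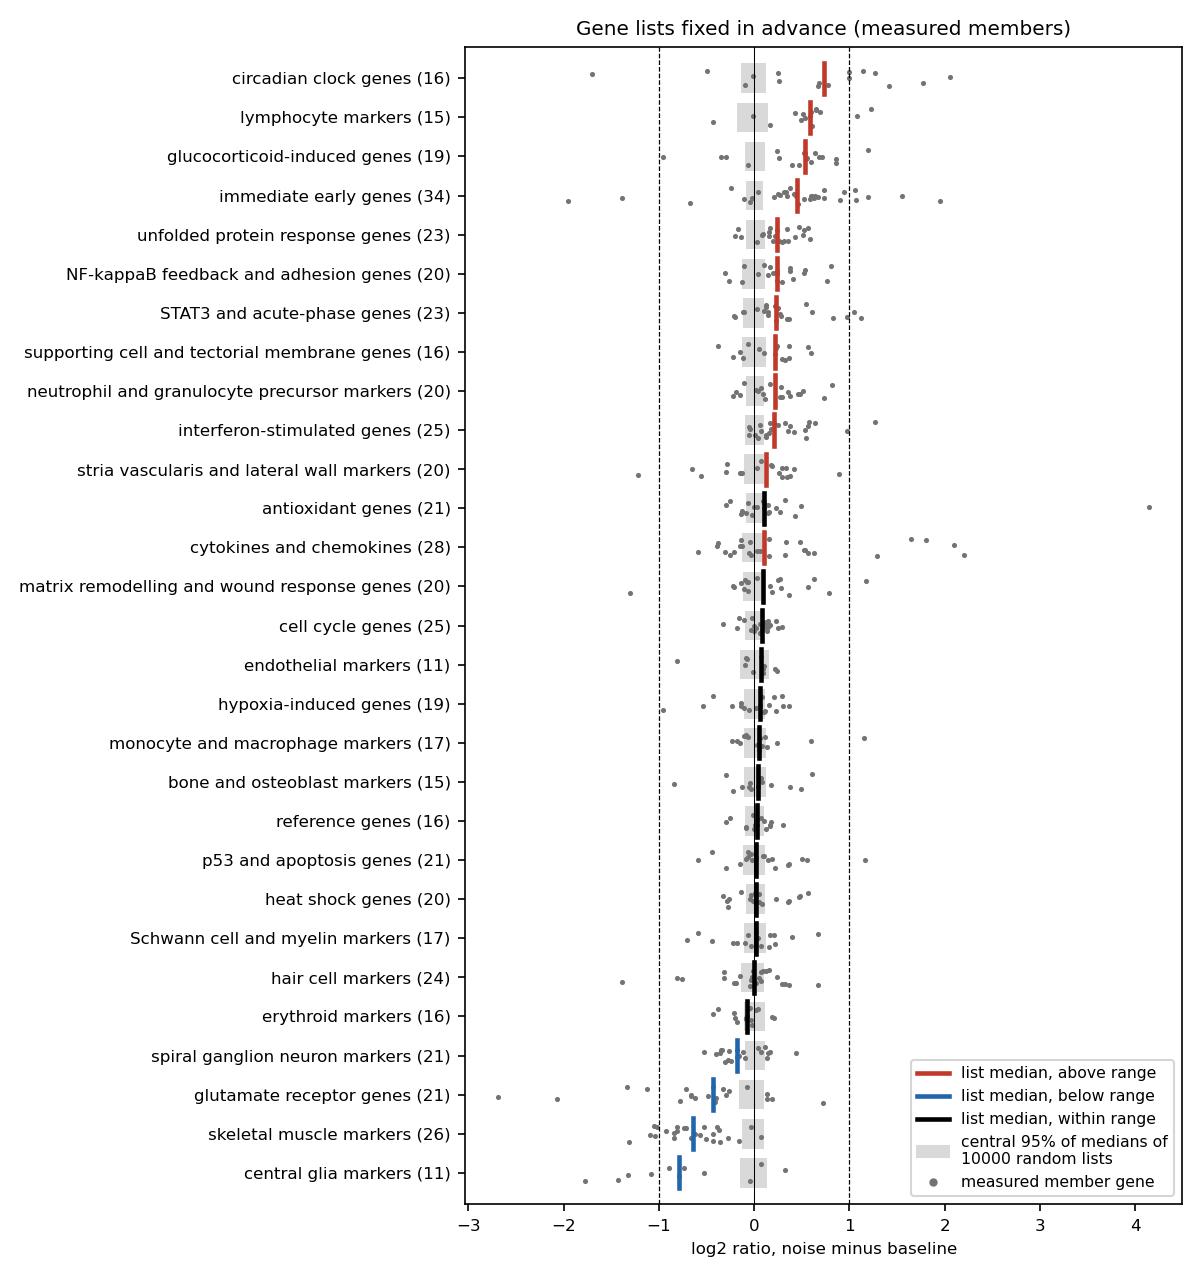
Log2 ratio (noise minus baseline) of the measured members of each of the 29 lists (grey points), with the list median (vertical bar) and the central 95% of the medians of 10000 level-matched random lists (grey box), and dashed lines at 2-fold. Medians run from -0.79 (central glia) to 0.73 (circadian clock), with 12 above their box, 4 below and 13 within.

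Of the sensory epithelium, hair cell markers lay within their random range, and supporting cell and tectorial membrane genes lay above theirs. Hair cell markers had a median of 0.00 (random range -0.14 to 0.10), with 12 of 24 above 0 and 12 below. The transduction channel gene Tmc2 was the only member past 2-fold (-1.39), at signals of 8.30 and 19.1 near the lower limit of measurement, and was at -0.38 with the normexp background. Slc26a5, which encodes the outer hair cell motor prestin, was at -0.75 with signals of 5.62 and 8.35 (0.11 with no filter on dim probes), and the hair cell factor gene Pou4f3 was at 0.67. Supporting cell and tectorial membrane genes had a median of 0.22 (-0.13 to 0.13), with 11 of 16 above 0, with Otoa at 0.60 and Ceacam16 at 0.57, both tectorial membrane genes, and none past 2-fold. Stria vascularis and lateral wall markers had a median of 0.12, just above the random range (-0.11 to 0.11), the potassium channel gene Kcnj10 being at -0.56, the melanocyte gene Tyr at 0.89 and the fibrocyte factor gene Pou3f4 at -1.22. The supporting cell median lay within the random range with the normexp background (0.053) and with the brightest probe (0.045), as did the lateral wall median with the normexp background (0.037), and Pou3f4 was at -0.55 with it, -0.72 with no filter on dim probes and -0.99 with spike-in scaling.

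Glutamate receptor genes and spiral ganglion neuron markers were lower after noise as groups. Glutamate receptor genes had a median of -0.43 (random range -0.16 to 0.11), with 17 of 21 below 0 and 4 at least 2-fold lower, among them Grin2a (-2.07), Grm5 (-1.33) and Grin2c (-1.13). Spiral ganglion neuron markers had a median of -0.18 (-0.10 to 0.11), with 14 of 21 below 0, none past 2-fold and Slc17a7, a vesicular glutamate transporter gene, lowest at -0.52; with spike-in scaling this median was 0.039, and with the brightest probe -0.093, both below its random lists. Schwann cell and myelin markers were within the random range, with a median of 0.01 and none of 17 past 2-fold. Central glia markers, genes of astrocytes and oligodendrocytes, were lower together with these lists. Their median was -0.79 (-0.15 to 0.14), and 4 of 11 were at least 2-fold lower, Slc1a2 (-1.78), Olig1 (-1.43), Olig2 (-1.32) and Aldoc (-1.08). With the normexp background Grin2a (-0.53), Grm5 (-0.47), Grin2c (-0.80) and Olig2 (-0.41) were under 2-fold and the central glia median was -0.49, and the 2 Grm5 probes differed (-2.29 and -0.38). With its brightest probe or the stricter filter Grm5 was at -0.38. Slc1a2 was at -0.95 with no filter on dim probes, Aldoc at -0.90 with its brightest probe and -0.86 with spike-in scaling, and Grin2c at -0.91 with spike-in scaling.

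Skeletal muscle markers were lower after noise in 25 of 26 measured genes, with a median of -0.64 (random range -0.13 to 0.10). Of these, 5 were at least 2-fold lower, the most for myoglobin (Mb) at -1.32 and the myosin heavy chain genes Myh1 at -1.09 and Myh2 at -1.05. The others, Ckm (-1.04) and Myh4 (-1.02), were under 2-fold with the normexp background (-0.52 and -0.41) and with spike-in scaling (-0.82 and -0.80). Myh4 was also just under 2-fold with median scaling, quantile normalization and loess on level. Myh2 was at -0.87 with the normexp background, -0.37 with no filter on dim probes and -0.83 with spike-in scaling, with which Myh1 was at -0.87. Of 6 lists of further tissue markers, written after the data were seen and in part from genes already seen to differ, 5 were lower as well, and noradrenergic neuron markers were higher (median 0.79, 4 of 8 at least 2-fold). The lower medians were -1.41 for adipocyte markers (16 of 22 at least 2-fold lower, the brown-fat gene Ucp1 at -2.81), -1.22 for pituitary markers (5 of 9), -1.23 for central neuron markers (8 of 16), -0.34 for choroid plexus markers (4 of 9, transthyretin, Ttr, at -2.36) and -0.33 for middle ear and airway epithelium markers (1 of 8). Leaving out the members of the 5 lower lists and of the muscle, central glia and glutamate receptor lists, 286 genes were at least 2-fold lower. The lists hold only chosen markers, so this count does not measure how many lower genes belong to those tissues.

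**Figure D3:**
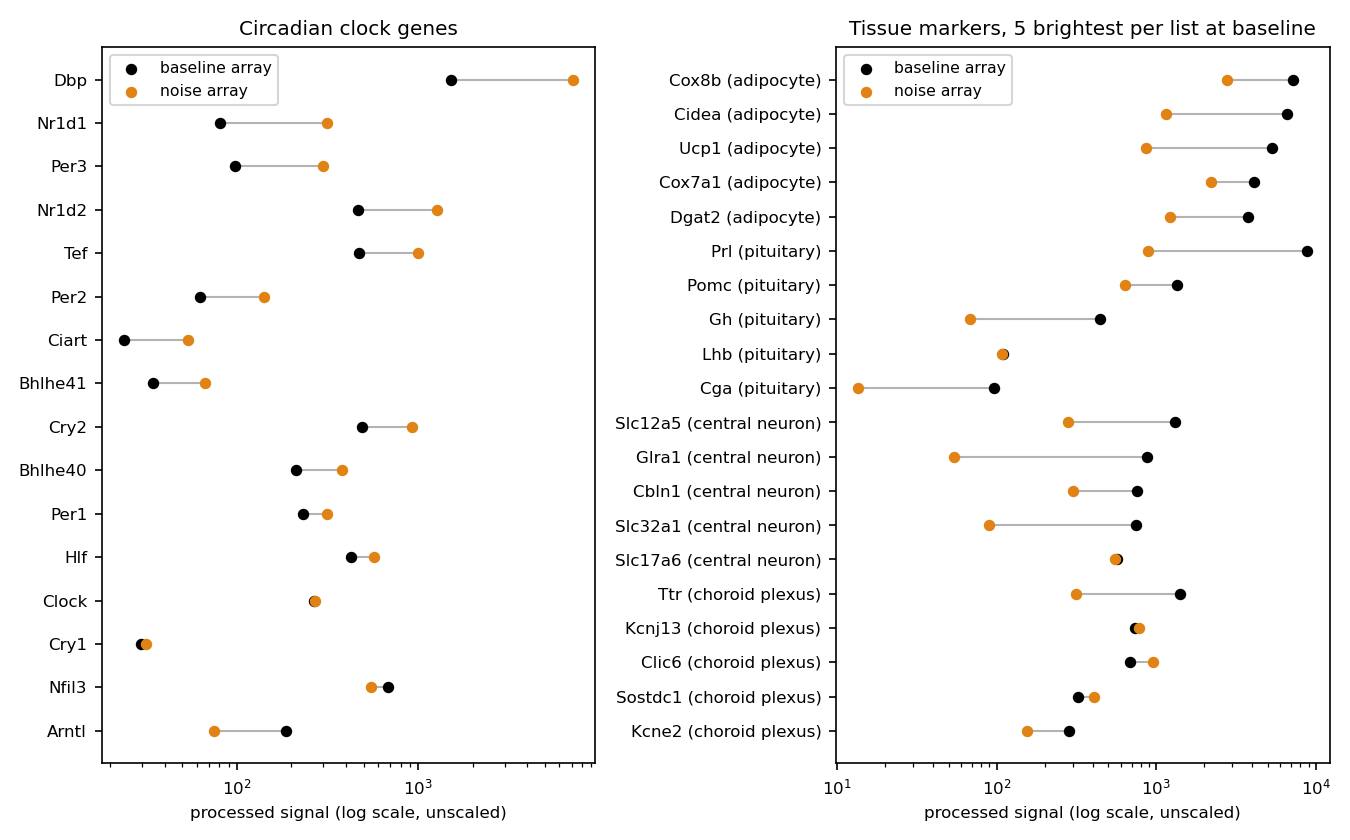
Processed signal (log scale, not scaled between arrays) on the baseline array (black) and the noise array (orange), for the 16 measured circadian clock genes (left) and the 5 measured markers brightest at baseline of each of 4 tissue lists (right). Dbp reached 7133 after noise against 1509 at baseline, while Prl was at 882 after noise against 8829 at baseline.

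Among lists of blood cells and their precursors, lymphocyte markers had a median of 0.58 (random range -0.18 to 0.14), with 13 of 15 above 0, and the median was 0.21 with the normexp background, still above its random lists. The B-cell precursor gene Vpreb1 was past 2-fold at 1.08, with Vpreb3 at 0.69 and Cd79b at 0.61. Pax5 was at 1.22 from 2 probes that differed (0.07 and 2.38), and was under 2-fold with its brightest probe or the stricter filter (0.07). Neutrophil and granulocyte precursor markers had a median of 0.22 (-0.08 to 0.10), with 16 of 20 above 0, none past 2-fold and the chemokine receptor gene Cxcr2 highest at 0.82, while the abundant granule genes S100a8 and S100a9 were at 0.03 and -0.15. Monocyte and macrophage markers (median 0.05) and erythroid markers (-0.07) were within their random ranges. In the macrophage list the hemoglobin scavenger receptor gene Cd163 was past 2-fold at 1.16, with probes at 0.71 and 1.61 and a value of 0.58 with the normexp background. Endothelial markers (0.07), bone and osteoblast markers (0.04) and reference genes (0.03) were also within range, and Actb was at -0.30 and Gapdh at 0.03.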

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

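Spike-in scaling and the counts without the tissue or clock lists were chosen after the results were seen, and the other alternatives before. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The counts at least 2-fold higher and lower (162 and 332) were 56 and 74 with the normexp background, whose offset of 50 shrinks ratios of dim probes by construction, 672 and 1296 over 37067 genes with no filter on dim probes, and 351 and 186 with spike-in scaling. With the stricter filter, which left 22163 genes, 185 were lower, and 1.5-fold and 3-fold rules gave 800 and 1325, and 28 and 84. The other 13 recomputed counts lay within 1.5 times the main ones. Among them, the counts from the authors' table (162 and 332) were fixed by its scale. Leaving out the tissue or clock lists (286 lower and 157 higher) could remove only members of those lists. Of 290 recomputed list medians, 283 kept their place relative to random lists and, where they stood apart from them, their sign. Median scaling and spike-in scaling move every gene by the same amount, and the authors' table has the main scale. Under these settings a list's place could not change beyond rounding, so their part of the 283 was fixed in advance. In all, 9 medians changed sign, of which 8 lay within the random range, among them hypoxia-induced genes (-0.045 with the brightest probe) and erythroid markers (0.15 with spike-in scaling). The remaining one, the spiral ganglion median, changed sign with spike-in scaling (0.039), which moved every gene upward by the same amount, and stayed below its random lists. With the brightest probe the cytokine median (0.062) and the supporting cell median (0.045) came to lie within the random range and the matrix remodelling median (0.13) above it. With the normexp background the supporting cell (0.053) and lateral wall (0.037) medians came to lie within it, and with the stricter filter the antioxidant median (0.11) lay above it; the cause of these moves was not tested. The naming rule took 46 genes past 2-fold that were measured on both arrays. List members named after their values were seen, such as Fos, Il6, Grin2c and Aldoc, are not counted among them. Of these 46, 14 were under 2-fold with the normexp background and 4 each with the brightest probe and with no filter on dim probes. With spike-in scaling 3 were so, and with the stricter filter 6 were no longer measured (Lipf, Cga, Egr4, Tmc2, Grin2a and Olig2) and 3 were under 2-fold (Fkbp5 0.86, Grm5 -0.38 and Pax5 0.07). None of those measured changed sign under these alternatives. Signal over background limits the dimmest of these genes, since the lowest processed signals well above background were 4.58 (noise) and 4.35 (baseline).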

Other observations

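The tests on unseen marker genes of fat, pituitary, brain and choroid plexus were written before their results were seen, and the marker lists themselves and all other tests here after the pattern was seen. Where a spread is given below for a gap between 2 lists, it is 2 times the sum of their random lists' SDs. For surrounding spots, the standard error of their median takes the place of the second SD. Such a spread describes draws of genes from these 2 arrays and not variation between animals. Markers of noradrenergic neurons were higher after noise. Dbh, the enzyme that makes noradrenaline, had a log2 ratio of 3.31 (9.93-fold), Phox2a 1.53, Th, the first enzyme of catecholamine synthesis, 1.31 and Slc18a2, the vesicular monoamine transporter gene, 0.41, and all 8 measured markers lay above 0, 4 of them at least 2-fold higher. The median of the 7 markers whose values had not been seen was 0.58, against a random range of -0.31 to 0.22. Markers of middle ear and airway epithelium differed among themselves: Bpifb1 was at -5.20, while the very bright Bpifa1 was at -0.35, and the median over all 8 was -0.33 (random range -0.21 to 0.17).

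Transcripts of organs next to the cochlea were higher in the baseline sample, and more of these tissues in its dissection is a candidate explanation. Among markers whose values had not been seen, medians lay below the random range for adipocytes (-1.01, 13 genes), pituitary (-0.74, 6 genes), central neurons (-0.82, 11 genes) and choroid plexus (-0.30, 7 genes), and of all 4 lists 1 gene stood in a list fixed in advance; bright genes among the lower ones were Cox8b (baseline signal 7135, log2 ratio -1.54), Pomc (1343, -1.25), Cbln1 (756, -1.51) and Ttr (1412, -2.36, seen before). Markers above 0 were Plin4 (0.30) of fat, Ghrhr (0.68) of the pituitary, where Tbx19 was well above background on the noise array only, Nrgn (0.29) of central neurons, and Clic6 (0.30) and Sostdc1 (0.16) of choroid plexus, and those near 0 included Lep (-0.07), Lhb (-0.22), Slc17a6 (-0.23) and Kcnj13 (-0.09). The median of the spiral ganglion list lay 0.64 above the one of central neurons. This argues against a loss of spiral ganglion transcripts as the whole cause only if no other neurons raised the spiral ganglion list. Noradrenergic neuron markers were higher after noise, and whether such neurons carry genes of that list was not tested. An effect of noise on the transcripts of the organs next to the cochlea was not tested, and no sort or gate is described that would have removed other tissue.

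Clock genes were split into arms after their values were seen, so the split is no independent evidence of opposite movement. Of the 16 measured members of the clock list 12 lay above 0 and 4 below, and not all of them were placed in an arm. All 10 measured genes driven through E-box or D-box elements lay above 0 (median 1.07, 5 past 2-fold), and all 4 of the Bmal1 arm below 0 (median -0.29, just inside its random range), a difference of 1.36. The first arm lay 0.94 above cochlear lateral wall markers, beyond the spread of 0.28, but this arm was formed after its values were seen. The whole clock list, fixed in advance, had a median of 0.73, against 0.12 for the lateral wall markers. Those 2 medians argue against a lower share of other tissue in the noise sample as the whole cause, though no spread was computed for their gap. More of some other tissue in that sample was not tested for these genes and stays open. A different clock hour at dissection and an effect of noise on the clock cannot be told apart, because the labels give no clock hour for either sample.

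The stress and inflammatory transcripts may reflect the noise exposure, a hypothesis from 1 array per group that competes with others left open. A local defect that reached surrounding spots is argued against as the whole cause. The 130 measured members of the immediate early, cytokine, NF-kappaB, STAT3 and interferon lists had a median of 0.26. These 5 stress and inflammatory lists were grouped after the pattern was seen. Each stood above its random range, so 0.26 is no independent evidence of a rise. Left out were unfolded protein response (0.24) and glucocorticoid-induced genes (0.53), above range. Antioxidant (0.11), heat shock (0.02), hypoxia-induced (0.06) and p53 genes (0.02), within range, were left out too. The spots within 3 rows and 3 columns of the members' spots had a median of -0.0068, a difference beyond the spread of 0.060. A lower share of other tissue in the noise sample is not excluded, since the members' median lay 0.14 above the lateral wall median, within the spread of 0.16, and more noradrenergic nerve tissue stays open too, with its unseen markers at 0.58, though whether it carries these transcripts was not tested. Blood is not excluded either: the erythroid median of -0.072 lay within its random range, but markers as bright at baseline as Hba-a2 (signal 123585) would hide a small share. The lymphocyte (0.58) and neutrophil (0.22) medians lay above their random ranges, but both lists also hold genes of precursor cells, so they do not single out blood. Differences between animals and in handling stay open, since each group held 1 sample.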
